A study of Mus musculus with 35 samples.

How the data were processed

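Gene expression was measured by bulk RNA sequencing in astrocytes sorted by flow cytometry from the cortex of Aldh1l1-eGFP mice at postnatal day 30 to 35, in 35 libraries. In these mice a green fluorescent protein is made under the control of Aldh1l1, a gene of astrocytes, and the sorted cells were taken 3, 24 or 72 h after lipopolysaccharide (LPS, 5 mg/kg) or saline. RNA was isolated with a column kit, amplified with SMART-seq HT chemistry, made into libraries with Nextera XT and sequenced on a NovaSeq instrument, per the labels.

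The deposited table gives FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each gene and library, which the authors made with HISAT2 and StringTie on mouse genome build mm10. The authors also gave a log2 fold change and an adjusted p-value for each of 6 comparisons, made with DESeq2 per the submitters' processing notes. The direction of their sex columns (female over male) was read from the Y-linked genes. Tool versions, and whether the authors shrank their fold changes, are not stated. Raw counts were not used here, so the depth in reads is unknown and no counting interval or floor is given. A value of 0 is therefore described as listed at 0, with no fold against it.

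The table held 19584 entries, of which 11 repeated a gene identifier. The first of each was kept, which left 19573 genes. FPKM differed within 6 of these repeats. The smallest mean FPKM over the libraries was 0.500012, in keeping with a minimum mean of 0.5 applied by the authors. Spreadsheet dates had replaced 20 gene symbols, which were restored from the Ensembl identifier. Positions come from GENCODE release M21 on GRCm38 (mm10), in which 19556 identifiers were found. FPKM summed to between 456417 and 565592 per library. Between 14508 and 16942 genes reached an FPKM of 1. Genes of the mitochondrial genome took 4.86% to 24.4% of the sum, and Pearson correlations of log2 values between libraries of a group, across genes, ran from 0.861 to 0.972.

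The 8 groups were set from the labels: female saline at 3 h (n = 4), female LPS at 3 h (n = 5), female saline at 24 h (n = 5), female LPS at 24 h (n = 4), male saline at 24 h (n = 5), male LPS at 24 h (n = 5), female saline at 72 h (n = 4) and female LPS at 72 h (n = 3). Each time and sex had saline libraries of its own. The labels do not state whether each library came from a separate animal, so p-values measure the spread between libraries only. The deposited values have 2 number formats, judged on values above 100. In 11 libraries, all from 24 h, these equalled rounded single-precision numbers within an absolute difference of 1e-07. In 24 libraries most of them did not, and these are called double-precision libraries. The single-precision libraries were replicates 1 to 3 of female saline, male saline and female LPS, and replicates 1 and 2 of male LPS. The format was treated as a batch. At 24 h, values within each format are given for the always-named genes that passed the test and for most of the gene lists described.

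Genes with an FPKM of at least 1 in at least 3 libraries were tested (19426 genes). A linear model with 1 coefficient per group was fitted to log2(FPKM + 1) of all libraries with limma 3.58.1 (lmFit, contrasts.fit, eBayes with an intensity trend, two-sided moderated test). P-values were adjusted by Benjamini and Hochberg within each of 11 contrasts, and genes with an adjusted p under 0.05 are called higher or lower. The contrasts were LPS against saline for each time and sex, the differences between these LPS effects (sexes at 24 h, 24 h against 3 h, 72 h against 24 h), the sexes within saline and within LPS, and saline libraries between times. All log2 fold changes and their standard errors (SE) come from this fit, and group values are mean FPKM ± SD.

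There were 34 gene lists, of which 11 held markers of other cell types. They were written from textbook knowledge before the data were examined, as were the groups, the test, the threshold and the rule for naming genes. Each list was tested against all other genes with camera (limma) at a preset correlation between genes of 0.01, and again with an estimated correlation. Both were adjusted over the lists of the contrast. Members called are counted over all genes tested and, with the adjustment redone, over the list alone. Members of one list can be in another. The rule named, for each LPS contrast, the 10 genes with the largest rise and the 6 with the largest fall among called genes whose LPS and saline libraries did not overlap, leaving out 6363 clone and predicted symbols and pseudogenes. It also named the 3 most changed called members of each list that passed camera, the 2 most changed called members of the other lists, and always Lcn2, Serpina3n, Gfap, Vim, Cxcl10, C3, Aldh1l1, Aqp4 and Slc1a2. For the other contrasts it named up to 6 genes per direction, and for the sexes Xist, Ddx3y, Uty, Kdm5d and Eif2s3y. Overlaps of called genes were tested with a one-sided Fisher's exact test among the genes tested.

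A marker score per library is the mean log2(FPKM + 1) of the measured markers. In all, 15 measures per library were compared in 6 comparisons with exact permutation tests, two-sided, and adjusted over the 90 tests. In these permutation tests 0 of the 90 adjusted p-values were under 0.05, and the smallest was 0.0752. The procedure was checked on simulated data made by planting changes of log2 1 or log2 2 in 200 genes. The simulated noise was normal and independent between genes, with no structure between libraries such as number format or mitochondrial share. The rates that follow do not cover such structure. The share of planted genes recovered at log2 1 and log2 2 was 47% and 93% for 3 h, 42% and 95% for 24 h females, 49% and 98% for 24 h males, and 29% and 89% for 72 h. For the difference between sexes it was 11% and 78%. Of the genes called in these simulations, 6.45%, 2.80%, 9.58% and 5.56% were not planted in the same order of contrasts, and 2.17% for the difference between sexes.

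Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at FPKM 5, rescaling every library to an equal FPKM sum, median-of-ratios rescaling, fits of only the groups compared, library quality weights, a replicate block, a minimum absolute log2 fold change of 1, the estimated correlation, the authors' adjusted p, and leaving out each library in turn. Alternatives chosen after seeing the data were the number format as a covariate, single-precision or double-precision libraries only, the log2 mitochondrial share as a covariate, leaving out the 2 libraries with the fewest genes, leaving out the 4 libraries from 3 and 72 h with a mitochondrial share under 10%, and protein-coding genes only. Other splits of the libraries into groups of the same sizes were drawn up to 100 per contrast. The work used R 4.3.3, the package data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.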

Results

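Astrocytes are the supporting glia of the brain, and LPS is a bacterial cell wall component that sets off systemic inflammation. The data are FPKM of 19573 genes in 35 libraries of sorted cortical astrocytes from mice given LPS or saline. Females were sampled at 3 h (5 LPS and 4 saline libraries), 24 h (4 and 5) and 72 h (3 and 4), and males at 24 h (5 and 5). The labels pose the question of how astrocytes respond over time after LPS and, at 24 h, in each sex. The cells had high levels of astrocyte genes: in female saline libraries at 3 h, Slc1a2, the main glutamate transporter, was at 801 ± 48.6 FPKM and Aqp4, a water channel, at 227 ± 10.1 FPKM (SD, n = 4). Neither of these genes, nor Aldh1l1, passed the test in any of the 4 LPS contrasts.

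At 3 h, astrocyte libraries from LPS-treated females had high levels of chemokine, interferon-response and acute-phase transcripts. Cxcl10, a chemokine that attracts T cells (chromosome 5, 92346638 to 92348889), rose from 1.0 ± 0.292 to 414 ± 231 FPKM (n = 4 saline and 5 LPS; log2 fold change 7.46 ± 0.47 SE, adjusted p = 5.97e-13). Lcn2, an iron-siderophore binding protein of reactive astrocytes (chromosome 2, 32384633 to 32388252), rose from 0.174 ± 0.163 to 86.5 ± 29.9 FPKM (log2 6.15 ± 0.57, adjusted p = 1.36e-09). Rsad2, an antiviral interferon-induced enzyme, rose by log2 5.31 ± 0.29 and Socs3, a feedback inhibitor of cytokine signalling, by 4.32 ± 0.30. Gfap, the intermediate filament raised in reactive astrocytes, rose from 176 ± 33.5 to 550 ± 216 FPKM (log2 1.55 ± 0.24, adjusted p = 6.1e-05), while Vim (log2 0.02, adjusted p = 0.985) and the complement gene C3 (log2 0.27, adjusted p = 0.718) did not pass.

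Of 37 interferon-response genes 32 rose at 3 h (35 adjusted over the list alone, median log2 2.20), among them Rsad2, Gbp2 (4.52 ± 0.41) and Iigp1 (4.37 ± 0.40), both interferon-induced GTPases. Of 24 cytokines and chemokines 16 rose (18 adjusted over the list alone, median 2.52), led by Cxcl10, Cxcl1 (5.76 ± 0.46) and Ccl12 (5.07 ± 0.59). Of 15 NF-kB targets and feedback genes 11 rose (14 adjusted over the list alone, median 1.65), including the adhesion molecule Icam1 (3.95 ± 0.28). Bcl3 was listed at 0 in all saline libraries and at 9.06 ± 1.30 FPKM after LPS. STAT3 and acute-phase genes rose in 10 of 14 cases (12 adjusted over the list alone, median 2.49), with Lcn2, Socs3 and Cebpb (3.52 ± 0.75). For MHC class I presentation 8 of 18 genes rose (14 adjusted over the list alone, median 1.12), with H2-Q6 (2.58) and the immunoproteasome subunit Psmb8 (2.25) in front. The glucocorticoid-response list had 5 of 12 genes higher (8 adjusted over the list alone, median 0.86), led by Map3k6 (2.89 ± 0.51) and Fkbp5 (2.57 ± 0.45). These 6 lists passed camera with the estimated correlation as well, with adjusted p = 7.64e-06, 8.69e-05, 8.84e-06, 2.06e-04, 0.0137 and 0.00881 in the order given.

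Among reactive-astrocyte panels at 3 h, 7 of 13 pan-reactive genes rose (12 adjusted over the list alone, median log2 1.55, adjusted p = 0.0017 with an estimated correlation). Of 11 measured A1 panel genes, a set first described as raised by LPS, 5 rose (9 adjusted over the list alone, median 1.35, adjusted p = 0.00659 with an estimated correlation). Of 9 A2 panel genes, a set first described after ischemia, 4 rose (4 adjusted over the list alone, median 0.34, adjusted p = 0.0633 with an estimated correlation), with Cd14 (3.93 ± 0.44), Ptgs2 (2.92 ± 0.34) and Ptx3 (2.12 ± 0.46) the 3 largest. Glycolysis genes rose in 2 of 17 cases, Pfkfb3 (1.41 ± 0.24) and Hk2 (1.07 ± 0.21), and that list had adjusted p = 0.491 with an estimated correlation. Immediate early genes, which tissue dissociation also raises, rose in 4 of 20 cases (8 higher and 2 lower adjusted over the list alone), led by Ier3 (3.11 ± 0.35) and Zfp36 (2.16 ± 0.32), with adjusted p = 0.491 with an estimated correlation. Of 16 complement genes only C2 rose (1.73 ± 0.41, adjusted p = 0.0929 without saline replicate 1), and the list did not pass (adjusted p = 0.0831).

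Some genes of microglia and endothelial cells were lower at 3 h. Gpr34 and P2ry12, receptors of microglia, fell from 28.4 ± 6.11 to 2.57 ± 1.94 FPKM (log2 -3.27 ± 0.51, adjusted p = 4.13e-05) and from 32.0 ± 6.18 to 8.03 ± 2.23 FPKM (log2 -1.88 ± 0.41, adjusted p = 0.00392). Without female LPS 3 h replicates 4 and 5, whose mitochondrial share was low (7.17% and 7.63%), P2ry12 no longer passed (log2 -1.68, adjusted p = 0.0606). The endothelial tight-junction gene Cldn5 fell by 2.34 on the log2 scale (SE 0.44), the transporter gene Slco1a4 fell by 2.29 (SE 0.29) and the receptor gene Tek fell by 1.46 (SE 0.30). In all, 2 of 19 microglia markers (2 adjusted over the list alone, median -0.55) and 4 of 15 endothelial markers fell (8 lower and 1 higher adjusted over the list alone, median -0.63). These lists had adjusted p = 0.309 and adjusted p = 0.152 with an estimated correlation. F13a1 was the 1 of 6 border macrophage markers that fell (-2.24 ± 0.57, adjusted p = 0.336 for the list with an estimated correlation), and it did not pass without saline replicate 1, saline replicate 4 or LPS replicate 5 (adjusted p = 0.111, 0.0501 and 0.0691). The iron exporter gene Slc40a1 fell by 2.19 (SE 0.29). Over whole libraries the microglia score was 3.10 ± 0.361 after LPS and 3.86 ± 0.394 in saline (exact permutation test, two-sided, p = 0.0159, the smallest possible, adjusted 0.0752 over 90 tests). The endothelial score was 2.65 ± 0.294 and 3.44 ± 0.174 (exact permutation test, p = 0.0159, adjusted 0.0752) and the border macrophage score 1.15 ± 0.745 and 2.36 ± 0.577 (p = 0.0476, adjusted 0.143).

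Neuron markers lay higher as a list with the preset correlation (0 of 14 called, median 0.39, adjusted p = 0.029) but not with an estimated one (adjusted p = 0.579), and that call was lost without any of 4 single libraries. Their score was 3.58 ± 0.194 after LPS and 3.24 ± 0.103 in saline (exact permutation test, two-sided, p = 0.0317, smallest possible 0.0159, adjusted 0.114).

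In total 376 genes were higher and 86 lower at 3 h (limma). With the estimated correlation 8 of 17 lists called kept an adjusted p under 0.05.

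**Figure D1:**
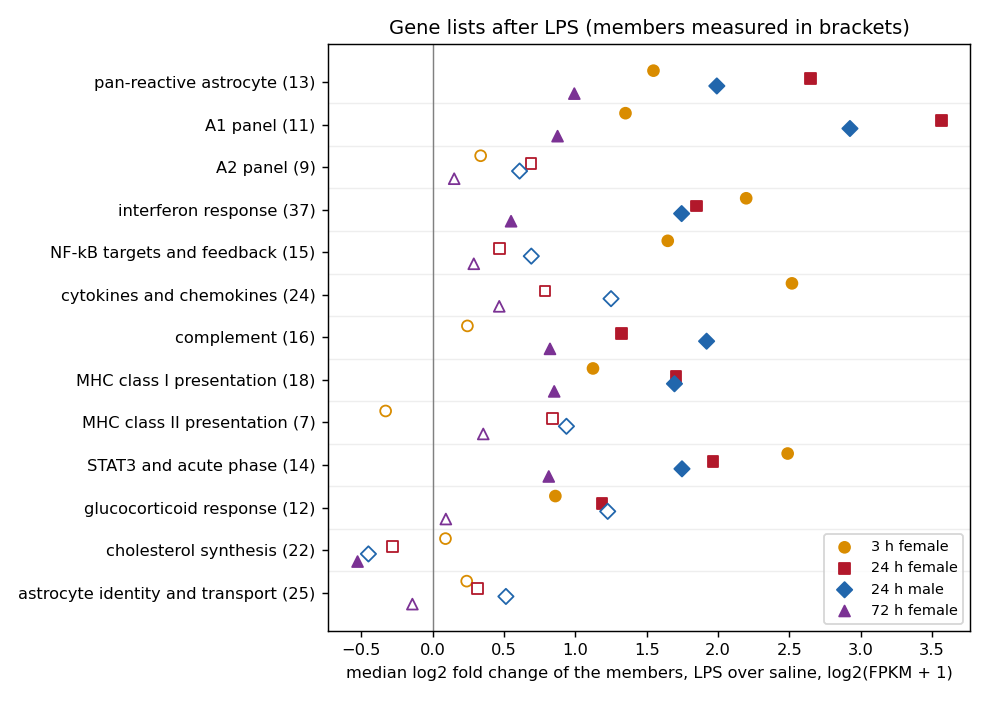
Median log2 fold change (LPS against saline, horizontal axis) of selected gene lists, with 1 colour and marker shape per time and sex. Filled points passed camera with both the preset and the estimated correlation. The A1 panel median was 1.35 at 3 h, 3.56 in 24 h females, 2.92 in 24 h males and 0.88 at 72 h.

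At 24 h, female astrocyte libraries had high levels of reactive-astrocyte, complement and antigen-presentation genes. Lcn2 rose from 0.216 ± 0.252 to 402 ± 123 FPKM (n = 5 saline and 4 LPS; log2 8.34 ± 0.57, adjusted p = 1.07e-11) and the serine protease inhibitor gene Serpina3n (log2 6.88 ± 0.49) from 5.37 ± 0.841 to 771 ± 221 FPKM. Saa3, an acute-phase protein gene, rose by 5.67 ± 0.79, the metalloprotease inhibitor gene Timp1 by 5.58 ± 0.49 and Serping1, the C1 inhibitor gene, by 5.08 ± 0.47. Gfap rose from 147 ± 16.4 to 892 ± 161 FPKM (log2 2.58 ± 0.24, adjusted p = 6.12e-09), Vim by 1.87 ± 0.31 and C3 from 0.00509 ± 0.00722 to 3.22 ± 0.519 FPKM (2.06 ± 0.25). Among single-precision and double-precision libraries, in that order, the log2 fold change of Lcn2 was 8.12 and 8.75, of Serpina3n 7.03 and 6.44, of Gfap 2.57 and 2.50, of Vim 1.88 and 1.93 (adjusted p = 0.377 in the latter), of C3 1.99 and 2.28 and of Cxcl10 3.07 and 4.45.

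In 24 h females 12 of 13 pan-reactive genes rose (12 adjusted over the list alone, median log2 2.65) and 10 of 11 A1 panel genes (11 adjusted over the list alone, median 3.56), each with adjusted p = 5.58e-05 with an estimated correlation. The largest A1 panel rises were Serping1, Fbln5 (5.02 ± 0.42), an elastic fibre gene, and Fkbp5 (3.91 ± 0.45). Complement genes rose in 7 of 16 cases (10 adjusted over the list alone, median 1.32), with C4b going from 14.4 ± 2.83 to 191 ± 101 FPKM (log2 3.42 ± 0.31). MHC class I presentation genes rose in 15 of 18 cases (18 adjusted over the list alone, median 1.71), with Psmb8 (3.76 ± 0.44), H2-T23 (3.74 ± 0.37) and H2-D1 (3.51 ± 0.43). Interferon-response genes rose in 29 of 37 cases (34 adjusted over the list alone, median 1.85), with Gbp2 (3.56 ± 0.41) and Oasl2 (3.30 ± 0.30). Further rises were in STAT3 and acute-phase genes, 9 of 14 (11 adjusted over the list alone, median 1.96) and glucocorticoid-response genes, 6 of 12 (8 adjusted over the list alone, median 1.19). These 5 lists had adjusted p = 2.88e-04, 6.11e-04, 1.42e-04, 2.1e-04 and 0.00345 with an estimated correlation, in the order given. Single-precision and double-precision libraries gave medians of 2.82 and 2.50 for the pan-reactive list, 4.04 and 2.93 for the A1 panel, 1.57 and 1.02 for complement, 1.81 and 1.33 for MHC class I, 1.77 and 1.72 for interferon, 2.28 and 1.32 for STAT3, and 1.73 and 0.15 for the glucocorticoid list.

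Other lists in 24 h females passed camera with the preset correlation and not with the estimated one. Of 24 cytokines and chemokines 7 rose (9 adjusted over the list alone, adjusted p = 0.117 with an estimated correlation), with Cxcl10 at log2 3.40 ± 0.47 and Ccl5 listed at 0 in all saline libraries. Of 15 NF-kB genes 3 rose (4 adjusted over the list alone, adjusted p = 0.101 with an estimated correlation), with Icam1 (2.51 ± 0.28) and Bcl3 (2.15 ± 0.28) the largest. Of 9 A2 panel genes 3 rose (4 adjusted over the list alone, adjusted p = 0.107 with an estimated correlation), with Slc10a6 first (2.85 ± 0.56). Of 7 MHC class II genes 3 rose (4 adjusted over the list alone, adjusted p = 0.159 with an estimated correlation), with H2-Ab1 first (2.43 ± 0.58, adjusted p = 0.0721 without LPS replicate 1). Of 11 metal and iron genes 3 rose (6 higher and 2 lower adjusted over the list alone, adjusted p = 0.188 with an estimated correlation), including Fth1, a ferritin chain (1.52 ± 0.28), and the metallothionein Mt1 (1.51 ± 0.24). Of 22 cholesterol synthesis genes 2 fell (5 adjusted over the list alone, adjusted p = 0.229 with an estimated correlation), among them Hmgcs1 (-0.83 ± 0.20, adjusted p = 0.0524 without LPS replicate 3). Single-precision and double-precision libraries gave list medians of 0.02 and -0.77. Of 86 cytosolic ribosomal protein genes 2 rose (2 adjusted over the list alone, adjusted p = 0.247 with an estimated correlation). Within the formats the medians were 0.63 and 1.41 for cytokines, 0.60 and 0.25 for NF-kB, 0.63 and 1.08 for the A2 panel, 1.19 and 0.49 for MHC class II (adjusted p = 0.0971 in the latter), 0.83 and 0.33 for metal and iron and 0.50 and 0.41 for ribosomal genes.

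Markers of other cells also differed in 24 h females. P2ry12 was lower by log2 -1.83 ± 0.41 (adjusted p = 0.00544), with -0.79 (adjusted p = 0.266) among single-precision and -4.26 among double-precision libraries. The hemoglobin genes Hbb-bt (-1.94 ± 0.51) and Hbb-bs (-1.65 ± 0.46) were the 2 of 5 erythroid markers that fell (4 adjusted over the list alone, adjusted p = 0.101 with an estimated correlation). S100a8 and S100a9, genes of neutrophils, were the 2 of 5 blood leukocyte markers that rose (3 adjusted over the list alone, adjusted p = 0.107 with an estimated correlation), S100a8 by 2.32 ± 0.54 (adjusted p = 0.056 without LPS replicate 3). Calls of Hbb-bt, Hbb-bs and S100a9 were lost when any of 5, 6 and 7 single libraries was left out, among them LPS replicate 3 (adjusted p = 0.122, 0.151 and 0.0948). The leukocyte score was 2.0 ± 0.579 after LPS and 0.749 ± 0.546 in saline (exact permutation test, two-sided, p = 0.0159, the smallest possible, adjusted 0.0752), a difference of 1.35 within single-precision libraries. The 1.54 within double-precision libraries rests on LPS replicate 4 alone, the highest of its group (2.87 against 1.69 to 1.75), and without it the preset call of the leukocyte list was lost. The erythroid list had medians of -1.23 and -1.35 and the leukocyte list of 1.14 and 1.86 within the formats. The score of fibroblast markers was higher after LPS, 1.73 ± 0.261 against 1.26 ± 0.152 (exact permutation test, p = 0.0159, the smallest possible, adjusted 0.0752; 0.568 and 0.210 within the formats), although that list did not pass camera (adjusted p = 0.121). The ependymal score was 0.653 higher (exact permutation test, p = 0.0635, smallest possible 0.0159, adjusted 0.159). None of these scores passed after adjustment. The preset camera call of the ependymal list (adjusted p = 0.0478) was lost in 9 of 24 alternatives, among them the estimated correlation (adjusted p = 0.38). Mitochondrially encoded genes had a median of -0.66 with no member called (adjusted p = 0.37 with an estimated correlation), and -1.24 and 0.60 within the formats.

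In 24 h females 494 genes were higher and 155 lower (limma), against 528 and 144 within single-precision libraries and 25 and 2 within double-precision libraries, where only 1 LPS library remained. Leaving out female LPS replicate 1 gave 315 higher and 76 lower, and leaving out replicate 4 gave 317 lower. Leaving out LPS replicates 2 and 3 and saline replicate 4, each in turn, gave 78, 72 and 100 lower.

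**Figure D2:**
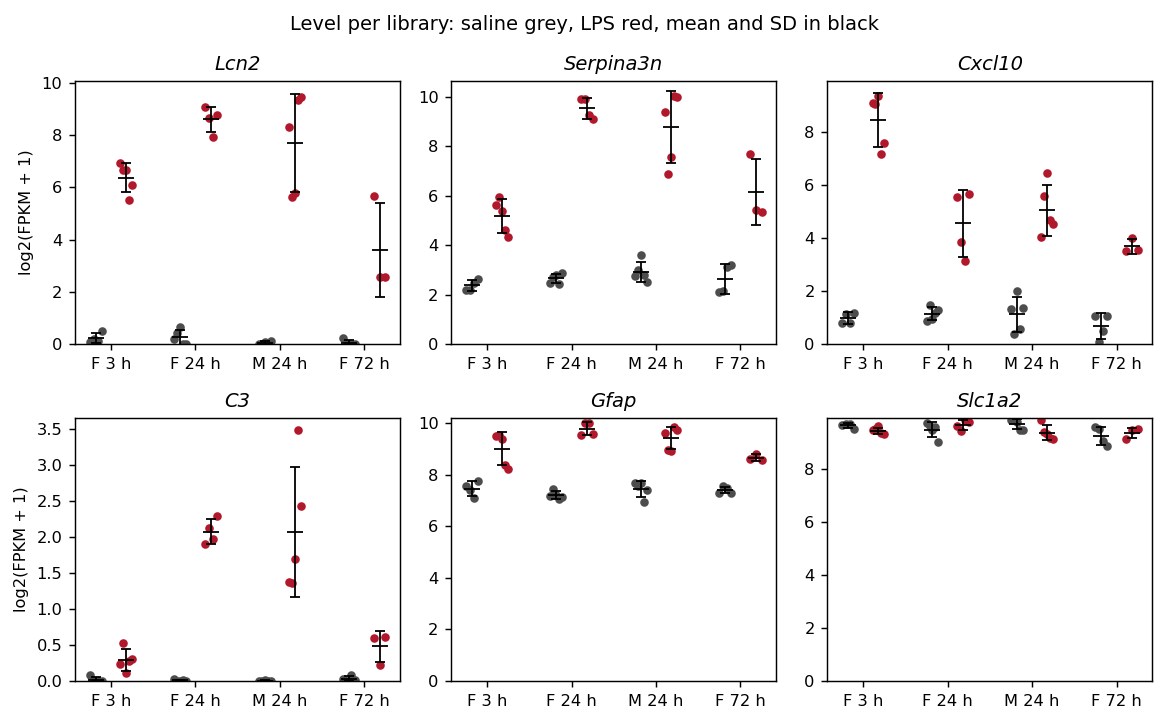
Expression as log2(FPKM + 1) on the vertical axis of Lcn2, Serpina3n, Cxcl10, C3, Gfap and Slc1a2 in each library (points; saline grey, LPS red), by time and sex, with the mean and SD of each group. Lcn2 was at 402 FPKM in 24 h LPS females against 0.216 in saline, and Cxcl10 at 414 FPKM at 3 h against 29.3 FPKM at 24 h.

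In males at 24 h the same panels rose. Lcn2 went from 0.0322 ± 0.0454 to 352 ± 312 FPKM (n = 5 and 5, log2 7.65 ± 0.54, adjusted p = 2.3e-11), and Serpina3n from 6.90 ± 2.46 to 608 ± 444 FPKM (5.84 ± 0.46). In LPS replicates 2 and 3 Lcn2 was at 47.8 and 54.4 FPKM, against 314, 646 and 700 in replicates 1, 4 and 5. Serpina3n was at 117 and 187 FPKM there, against 667, 1055 and 1015. Cxcl10 was instead highest in replicates 2 and 3 (46.7 and 86.8 FPKM). Saa3 was listed at 0 in all saline libraries and at 124 ± 65.4 FPKM after LPS. Timp1 rose by 4.41 ± 0.46, Serping1 by 4.27 ± 0.44, Ccl12 by 4.04 ± 0.56 and Cxcl10 by 3.93 ± 0.45. Gfap went from 177 ± 34.5 to 707 ± 201 FPKM (1.97 ± 0.23), Vim rose by 1.45 ± 0.30 and C3 by 2.06 ± 0.23. Among single-precision and double-precision libraries, in that order, the log2 fold change of Lcn2 was 6.92 and 8.13, of Serpina3n 5.01 and 6.55, of Gfap 1.66 and 2.33, of Vim 1.03 (adjusted p = 0.34) and 1.79, of C3 1.37 and 2.53, and of Cxcl10 3.56 and 4.27.

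Of 13 pan-reactive genes 12 rose in males (12 adjusted over the list alone, median 1.99), as did 10 of 11 A1 panel genes (11 adjusted over the list alone, median 2.92), 34 of 37 interferon-response genes (37 adjusted over the list alone, median 1.74) and 11 of 16 complement genes (12 adjusted over the list alone, median 1.92). Each of these 4 lists had adjusted p = 0.00367 with an estimated correlation. MHC class I genes rose in 16 of 18 cases (17 adjusted over the list alone, median 1.69, adjusted p = 0.0153 with an estimated correlation) and STAT3 and acute-phase genes in 10 of 14 (12 adjusted over the list alone, median 1.75, adjusted p = 0.00405 with an estimated correlation). Examples were Oasl2 (2.93 ± 0.28), C4a (3.28 ± 0.50), C4b (3.26 ± 0.30) and H2-D1 (2.96 ± 0.41). Within single-precision and double-precision libraries the medians were 1.75 and 2.29 for the pan-reactive list, 2.39 and 3.07 for the A1 panel, 1.59 and 1.73 for interferon, 1.47 and 1.63 for complement, 1.04 and 2.06 for MHC class I, and 1.41 and 1.91 for STAT3.

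With the estimated correlation the other lists of males did not pass. Among them was the immediate early and dissociation list (median 0.58), whose preset call was lost without any of 4 single libraries. Its medians were 0.28 (adjusted p = 0.682) and 0.73 within single-precision and double-precision libraries. Of 24 cytokines and chemokines 11 rose (17 adjusted over the list alone, adjusted p = 0.13 with an estimated correlation). So did 6 of 15 NF-kB genes (8 adjusted over the list alone, adjusted p = 0.09 with an estimated correlation), 7 of 12 glucocorticoid-response genes (8 adjusted over the list alone, adjusted p = 0.0717 with an estimated correlation) and 3 of 9 A2 panel genes (3 adjusted over the list alone, adjusted p = 0.454 with an estimated correlation). Of 22 cholesterol synthesis genes 7 fell and 1, Ebp, rose (adjusted p = 0.0591 without LPS replicate 5), and the list had 10 and 1 adjusted over the list alone and adjusted p = 0.166 with an estimated correlation. Hmgcs1 was at -0.98 ± 0.19. Of 86 cytosolic ribosomal protein genes 33 rose (61 adjusted over the list alone, median 0.67, adjusted p = 0.282 with an estimated correlation). Of 37 mitochondrially encoded genes 4 fell (23 adjusted over the list alone, median -1.23, adjusted p = 0.165 with an estimated correlation). The mitochondrial share of the libraries was 9.57 ± 5.17% after LPS and 19.6 ± 2.97% in saline (exact permutation test, two-sided, p = 0.00794, the smallest possible, adjusted 0.0752). Of 19 microglia markers 6 rose and 2 fell (10 and 2 adjusted over the list alone, adjusted p = 0.582 with an estimated correlation). Higher were Aif1 at 2.23 ± 0.40 and the complement genes C1qb (2.12 ± 0.53) and C1qa (2.02 ± 0.43), and P2ry12 (-1.57 ± 0.38) and Gpr34 (-1.55 ± 0.48) were lower. Gpr34 did not pass without saline replicates 2, 4 or 5 or LPS replicates 1, 4 or 5, left out in turn (adjusted p up to 0.0988). S100a8 and S100a9 were the 2 of 5 leukocyte markers that rose (2 adjusted over the list alone, adjusted p = 0.262 with an estimated correlation), with S100a8 at 2.75 ± 0.51. The fibroblast score was 2.21 ± 0.345 after LPS and 1.52 ± 0.258 in saline (exact permutation test, p = 0.0159, smallest possible 0.00794, adjusted 0.0752; 0.674 and 0.629 within the formats; list adjusted p = 0.146), and the ependymal score, 0.756 higher, did not pass after adjustment (p = 0.0397, adjusted 0.132; list adjusted p = 0.171).

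Single-precision and double-precision libraries of males gave medians of -0.41 and -1.81 for mitochondrially encoded genes, and the mitochondrial share differed by -5.57 and -14.7 percentage points. They gave 0.98 and 1.06 for cytokines, 0.50 and 0.94 for NF-kB, 0.83 and 1.59 for the glucocorticoid list, 0.55 and 0.70 for the A2 panel (adjusted p = 0.0939 in the latter), -0.56 and -0.17 for cholesterol synthesis and 0.67 and 0.63 for ribosomal genes. For microglia they were 0.89 and 0.82 (adjusted p = 0.098 in the latter) and for leukocytes 1.65 and 0.54 (adjusted p = 0.127 in the latter). P2ry12 was at -1.50 (adjusted p = 0.07) and -1.86. Smurf2, a ubiquitin ligase gene, fell by 1.59 (SE 0.28) and Dclk1, a kinase gene, fell by 1.55 (SE 0.34).

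In males 1376 genes were higher and 353 lower (limma; 20.4% lower), against 143 and 31 within single-precision and 383 and 50 within double-precision libraries. Median-of-ratios rescaling, which moved the median of all genes by -0.15, gave 751 higher and 633 lower (45.7% lower), and rescaling to an equal FPKM sum moved it by 0.11. The number higher was 590 without male LPS replicate 5, 715 without LPS replicate 4, 651 without saline replicate 5 and 783 without saline replicate 1. The number lower was 103, 140, 137 and 140 in the same order, and 202 without saline replicate 2.

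The responses of the sexes at 24 h were then compared. Of the genes called, 369 rose in both sexes where 35.0 would be shared by independent lists, and 56 fell in both (2.82 by independence; Fisher's exact test, one-sided, p = 5.78e-58). The 1 gene called in opposite directions, a clone symbol (RP24-562O19.2) chosen after its values were seen, was higher in females and lower in males. Across the 1952 genes called in either sex the log2 fold changes correlated with Pearson r = 0.818 and Spearman rho = 0.744, and across all 19426 genes tested, which were not chosen by a call, with r = 0.658 and rho = 0.595. This is across genes, which are not independent replicates. The test of the difference itself, male minus female LPS effect, called 0 genes with limma. An unadjusted p under 0.05 was found for 772 genes, fewer than the share of 0.05 of the 19426 tested genes that chance gives. The authors' table gives no test of the difference between the LPS effects. Without male saline replicate 4 the limma test called 1 gene. The A1 panel (median -0.81, preset adjusted p = 7.75e-06) and the pan-reactive list (median -0.61, preset adjusted p = 9.45e-04) were lower in males by camera, with adjusted p = 0.487 and adjusted p = 0.827 with an estimated correlation. Within single-precision and double-precision libraries the A1 median was -1.60 and 0.19 and the pan-reactive median -0.91 and -0.14. The double-precision values rest on 1 female LPS library, so a turn of direction between formats cannot be concluded. The single-precision values for males rest on LPS replicates 1 and 2. Replicate 2 had lower Lcn2 and Serpina3n (47.8 and 117 FPKM) than replicate 1 (314 and 667 FPKM). Median-of-ratios rescaling moved the all-gene median of this difference by -0.12.

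**Figure D3:**
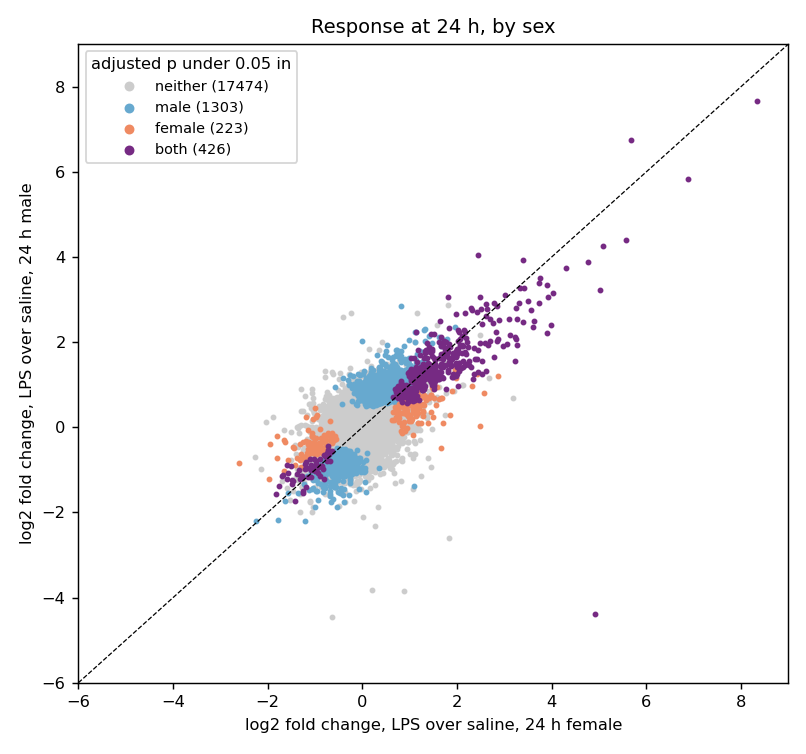
Log2 fold change of each tested gene 24 h after LPS in females (horizontal axis) and males (vertical axis), coloured by where it was called. There were 426 genes called in both sexes, 223 in females alone, 1303 in males alone and 17474 in neither.

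Saline males and females differed in sex-linked genes: 6 genes were higher in males and 4 lower (limma). The Y-linked Eif2s3y was at 103 ± 41.6 FPKM in males and 0.0322 ± 0.0508 in females (n = 5 and 5; log2 6.52 ± 0.23), and Ddx3y, Uty and Kdm5d were higher by 4.51, 4.26 and 3.62. Xist, the RNA that silences one X chromosome, was at 0.150 ± 0.127 FPKM in males and 74.2 ± 26.5 in females (log2 -5.97 ± 0.44), and its antisense Tsix differed by -4.83. Protein-coding genes alone gave 5. After LPS, 11 genes were higher and 3 lower in males (21.4% lower), and these included the same 6 sex-linked genes, with Bcas1, an oligodendrocyte gene (1.47 ± 0.24), and Sprn (1.35 ± 0.28), whose call was lost without any of 6 single libraries. Median-of-ratios rescaling moved the all-gene median there by -0.11 and the share lower to 42.9%. Leaving out male LPS replicate 1 gave 88 genes and leaving out female LPS replicate 4 gave 41.

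At 72 h, females had 15 genes higher and 0 lower. Saa3 was at 112 ± 80.7 FPKM after LPS and 0.194 ± 0.360 in saline (n = 3 and 4; log2 6.37 ± 0.90, adjusted p = 8.54e-04), Lcn2 at 19.8 ± 25.7 and 0.0433 ± 0.0867 FPKM (3.54 ± 0.65, adjusted p = 0.0102), Serpina3n at log2 3.52 ± 0.55 and Cxcl10 at 3.03 ± 0.54. The MHC class I genes H2-Q6 (2.68 ± 0.47), B2m (1.83 ± 0.37) and H2-Q7 (1.80 ± 0.29) rose. So did the leukocyte surface genes Cd52 (2.27 ± 0.40) and Ptprc (1.97 ± 0.38). The formyl peptide receptor gene Fpr1 (1.99 ± 0.36) rose, and the B cell chemokine gene Cxcl13 was listed at 0 in all saline libraries. Outside the naming rule, and chosen after their values were seen, Lat2 (1.78), Mpeg1 (1.44), Itgb2 (1.39) and Adcy7 (1.13) complete the 15. Without LPS replicate 1, Lcn2, Serpina3n, Cxcl10 and H2-Q6 did not pass (adjusted p = 0.229, 0.0612, 0.0561 and 0.0895). Without LPS replicate 3 neither did Cxcl10, H2-Q6, Cd52, Fpr1, Ptprc, B2m or H2-Q7 (adjusted p = 0.075, 0.135, 0.392, 0.443, 0.443, 0.455 and 0.0621). Calls of Ptprc and B2m were lost when any of 5 single libraries was left out, of Cd52 any of 3 and of Cxcl13 any of 2. Saa3 passed in each case. Gfap was at 404 ± 39.7 and 168 ± 14.9 FPKM and did not pass (1.26 ± 0.28, adjusted p = 0.0705), nor did Vim (0.58, adjusted p = 0.958) or C3 (0.45, adjusted p = 0.958).

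By list at 72 h, 3 of 13 pan-reactive genes rose (5 adjusted over the list alone, median 0.99, adjusted p = 0.0063 with an estimated correlation), 3 of 18 MHC class I genes (9 adjusted over the list alone, median 0.85, adjusted p = 0.00911 with an estimated correlation) and 3 of 14 STAT3 and acute-phase genes (4 adjusted over the list alone, median 0.81, adjusted p = 0.00756 with an estimated correlation). Complement genes (0 of 16 called, 2 adjusted over the list alone, median 0.82), A1 panel genes (0 of 11, 2 adjusted over the list alone, median 0.88) and interferon-response genes (0 of 37, 4 adjusted over the list alone, median 0.55) lay higher as lists, with adjusted p = 0.00863, 0.0243 and 0.0425 with an estimated correlation. Of 5 blood leukocyte markers 1 rose, Ptprc (4 adjusted over the list alone, median 1.97, adjusted p = 0.00159 with an estimated correlation). The leukocyte score was 2.73 ± 0.892 after LPS and 1.0 ± 0.165 in saline (exact permutation test, two-sided, p = 0.0571, the smallest possible with 3 and 4 libraries). Cholesterol synthesis genes lay lower as a list, with 0 of 22 called (1 adjusted over the list alone, median -0.53, adjusted p = 0.0482 with an estimated correlation). Cytokines and chemokines (1 of 24 called, adjusted p = 0.0587 with an estimated correlation), erythroid markers (0 of 5, median -1.75, adjusted p = 0.0535 with an estimated correlation) and microglia markers (0 of 19, median 0.73, adjusted p = 0.124 with an estimated correlation) lost their calls. In all, 8 of 24 lists kept theirs. Border macrophage, mural cell, fibroblast, oligodendrocyte and neuron markers and mitochondrially encoded genes were also among the lists that lost them.

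These counts came from limma, with 1046 genes at an unadjusted p under 0.05, and the authors' table lists 134 higher and 5 lower. The 1046 are close to the share of 0.05 of the 19426 tested genes that chance gives. The number higher was 3 without LPS replicate 3, 5 without LPS replicate 1, 25 without LPS replicate 2 and 8 without saline replicate 1, and leaving out LPS replicate 2 gave 1 lower. A fit of only these groups gave 2 higher, and library quality weights gave 997 higher and 2617 lower. Median-of-ratios rescaling moved the all-gene median by 0.10.

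Over time in females, 130 genes rose at both 3 h and 24 h (9.56 by independence; Fisher's exact test, one-sided, p = 4.55e-114) and 7 fell at both (0.686). Of the 15 genes higher at 72 h, 7 were also higher at 24 h (0.381; p = 3.56e-08 by the same exact test) and 6 at 3 h (0.290). A further count by time gave 245 genes called higher at 3 h alone, 362 at 24 h alone, 7 at 72 h alone and 5 at all 3 times. Hes1, a Notch target gene (log2 0.96 at 3 h and -1.07 at 24 h), and Irf2bp2 (0.63 and -0.69) were the 2 genes called in opposite directions, and both were chosen after their values were seen. The difference between the 24 h and 3 h LPS effects passed the test for 138 genes, 57 larger and 81 smaller at 24 h. Larger at 24 h were Fbln5 (4.88 ± 0.59), Serping1 (4.35 ± 0.67), the secreted glutathione peroxidase gene Gpx3 (4.29 ± 0.60) and Serpina3n (4.08 ± 0.69). Smaller were the chemokine genes Cxcl10 (-4.06 ± 0.67) and Cxcl1 (-3.94 ± 0.65), the cytokine gene Il6 (-3.60 ± 0.52) and Rsad2 (-3.49 ± 0.41). The effects on complement genes were larger at 24 h (4 of 16 called, median 1.41), and those on cytokines and chemokines (5 of 24 called, median -1.38) and NF-kB genes (1 of 15 called, median -1.10) smaller, with adjusted p = 0.00826, 0.00826 and 0.00547 with an estimated correlation. Without female LPS 24 h replicate 4 the count was 215, and within double-precision libraries, with 1 LPS library at 24 h, it was 30.

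From 24 h to 72 h the LPS effect differed for 67 genes, 4 larger and 63 smaller at 72 h. Smaller were Lcn2 (-4.80 ± 0.86), Fbln5 (-4.48 ± 0.63), Serping1 (-4.36 ± 0.71) and Timp1 (-4.34 ± 0.74). Larger were Fgfbp3 (1.73 ± 0.40), Hapln1 (1.58 ± 0.36), the cholesterol exporter gene Abca1 (1.32 ± 0.28) and Slco1c1 (1.29 ± 0.29). Their calls were lost when any of 10, 11, 6 and 11 single libraries was left out. Effects on A1 panel genes were smaller at 72 h (5 of 11 called, median -2.50, adjusted p = 0.033 with an estimated correlation), while the pan-reactive (5 of 13 called, adjusted p = 0.064 with an estimated correlation) and interferon lists (4 of 37, adjusted p = 0.0672 with an estimated correlation) lost their calls. The count was 259 without female LPS 24 h replicate 4. It was 26, 27 and 41 without its replicates 1, 2 and 3, 37 and 43 without female saline 24 h replicates 1 and 4, 27 and 25 without saline 72 h replicates 3 and 4, and 24 and 36 without LPS 72 h replicates 2 and 3. Within double-precision libraries it was 1, and median-of-ratios rescaling moved the all-gene median by 0.14.

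Saline libraries also differed between times. Endothelial genes were lower at 24 h than at 3 h, with 9 of 15 markers called (median -1.61, adjusted p = 0.013 with an estimated correlation), as were mural cell genes (3 of 8, median -1.10, adjusted p = 0.0322 with an estimated correlation) and cell cycle genes (1 of 16, median -0.80, adjusted p = 0.0369 with an estimated correlation). Ptgds, a prostaglandin synthase gene of barrier cells, was at 56.8 ± 47.0 FPKM at 24 h and 408 ± 154 at 3 h (n = 5 and 4; log2 -3.18 ± 0.51), and the mitotic kinase gene Pbk differed by -2.59 ± 0.50. Within double-precision libraries the endothelial median was -0.97, and the mural cell score differed by -0.651, against -1.02 with all libraries. All 3 h libraries were double precision. At 24 h the cell cycle and mural cell lists lay lower in single-precision libraries (medians -0.53 and -0.45). Part of these falls thus cannot be told apart from the number format. The call of the cell cycle gene Top2a was lost when any of 5 single libraries was left out. The 24 h libraries also had fewer genes detected, 15447 ± 630 against 16237 ± 99.9, and lower neuron and ependymal scores, by 0.705 and 1.01 (exact permutation test, two-sided, p = 0.0159 for each, the smallest possible, adjusted 0.0752). In all 7 genes were higher and 148 lower (limma). The total of 155 was 56, 93, 74 and 92 without 3 h saline replicates 1, 2, 3 and 4, 41, 43 and 55 without 24 h replicates 1, 2 and 3, and 4 within double-precision libraries.

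At 72 h, 568 genes were higher than in 24 h saline libraries and 23 lower (limma; 3.89% lower). More genes were detected in the 72 h libraries, 16606 ± 353 against 15447 ± 630 (n = 4 and 5; exact permutation test, two-sided, p = 0.0159, the smallest possible, adjusted 0.0752), a difference of 1377 among double-precision libraries. Among these were 15 of 19 microglia markers (median 1.96, adjusted p = 0.0455 with an estimated correlation), 10 of 15 endothelial, 7 of 12 oligodendrocyte, 5 of 8 mural cell, 5 of 9 oligodendrocyte precursor and 6 of 14 neuron markers (each adjusted p = 0.0286 with an estimated correlation). Mbp, a myelin gene, was at 539 ± 466 FPKM at 72 h and 75.5 ± 102 at 24 h (n = 4 and 5; log2 3.11 ± 0.84), C1qb differed by 2.55 ± 0.56 and Tmem119, a microglial gene, by 2.29 ± 0.45. Without 72 h saline replicate 4 these 3 did not pass (adjusted p = 0.236, 0.0997 and 0.0617), nor without replicate 3 did Mbp and C1qb (0.172 and 0.0679), nor Mbp without 24 h replicates 1, 2 and 3 (0.117, 0.0966 and 0.0613). The total of 591 was 33 without 72 h saline replicate 4, 121 without replicate 3, 904 without replicate 2, and 316 and 328 without 24 h replicates 1 and 2. It was 118 within double-precision libraries, 3 without the 2 libraries of low mitochondrial share and 0 in a limma fit of these 2 groups alone, which ends the call, and median-of-ratios rescaling moved the all-gene median by -0.19 and the share lower to 18.5%.

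**Figure D4:**
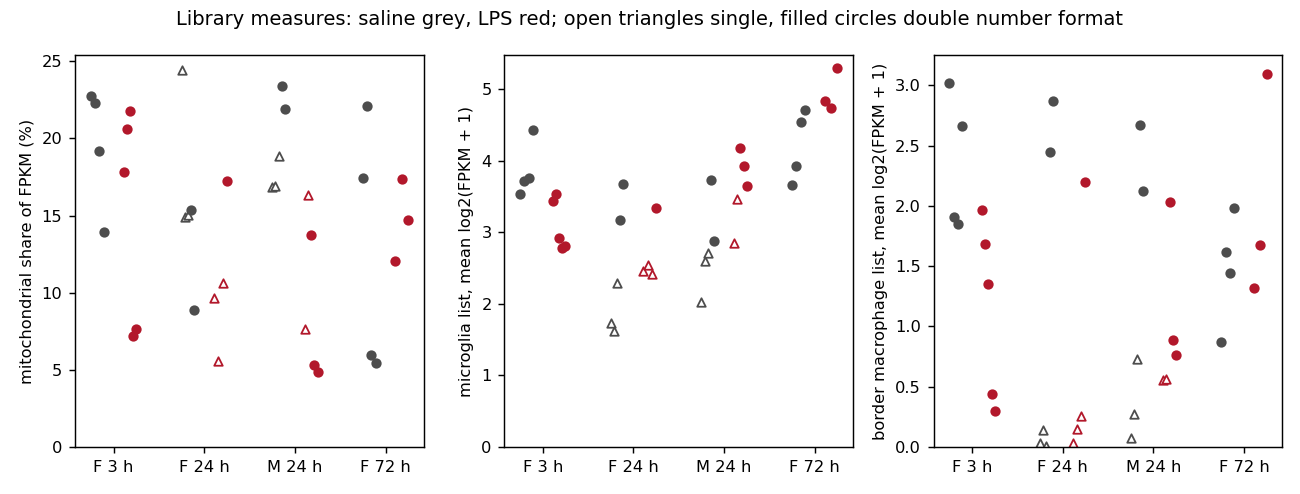
Mitochondrial share of FPKM (%), microglia marker score and border macrophage marker score (mean log2(FPKM + 1)) on the vertical axes for each library by group, with open triangles for single-precision and filled circles for double-precision libraries. Male LPS libraries had a mean mitochondrial share of 9.57% against 19.6% in male saline libraries.

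In the authors' own table, 489 genes were higher and 154 lower at 3 h, 541 and 266 in 24 h females, 1588 and 1809 in 24 h males and 134 and 5 at 72 h, at their adjusted p under 0.05. These lists held 382 of the 462 genes called here at 3 h, 526 of 649 in 24 h females, 1308 of 1729 in 24 h males and 14 of 15 at 72 h. None of the shared genes had opposite signs. The gene missing at 72 h is Lcn2, with no adjusted p and log2 0.49 in their table. At 24 h their log2 values for Lcn2 are 3.96 in females and 2.97 in males, against 8.34 and 7.65 here, and for C3 6.01 and 5.33, against 2.06 in both sexes here. How their values treat genes near 0 is not described, and the pseudocount of 1 lowers fold changes of such genes here, so the 2 scales differ for them. They also list as higher at 72 h Gfap (log2 1.20, adjusted p = 3.78e-05) and C3 (1.36, adjusted p = 0.00858), and C3 at 3 h (1.61, adjusted p = 0.0171), which did not pass here. Slc1a2 is lower in 24 h males in their table (log2 -0.519, adjusted p = 0.0457) and did not pass here. Between the sexes the authors' table lists 14 genes in saline and 175 after LPS, against 10 and 14 here.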

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

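All tests of explanations in this part were chosen only after the results they address had been seen.

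More genes were called in males than in females at 24 h, 1729 against 649 (ratio 2.66), although no gene passed the test of the sex difference itself (limma, 0 genes). The mitochondrial share of male libraries was 9.57% after LPS and 19.6% in saline without overlap, and with that share as a covariate the ratio was 0.389 (317 against 814 genes), so the share and LPS cannot be told apart in males. With the number format as a covariate the ratio was 2.58, within single-precision libraries 0.259 (174 against 672) and within double-precision libraries 16.0 (433 against 27), and too few libraries of each format keep that explanation open. The ratio was 1.07 and 1.32 without male LPS replicates 5 and 4, which had the lowest shares (4.86% and 5.32%), but also 1.21 without male saline replicate 5 (21.9%) and 1.42 without saline replicate 1 (16.8%, the lowest of its group), so its fall is not particular to the LPS libraries with low shares. Male LPS libraries also had more genes detected, 16405 ± 255 against 15765 ± 640 in male saline (exact permutation test, p = 0.0317, adjusted 0.114). The top 50 genes took 37.1 ± 8.17% of their FPKM, against 48.8 ± 4.14% in male saline (exact permutation test, p = 0.0397, adjusted 0.132). Neither measure was tested as a cause of the larger male count. A difference between the sexes stays open and untested by these values, and the larger male count may reflect library quality as well as sex.

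At 3 h after LPS, 2 of 19 microglia and 4 of 15 endothelial markers were lower, and neither list passed with an estimated correlation (adjusted p = 0.309 and 0.152). A lower number of those cells was tested on these members, chosen because they fell, with the mean of each list as a covariate. P2ry12 and Gpr34 both kept an adjusted p under 0.05 over all genes (median log2 fold change -2.01). With the covariate 3 other members of each list were higher. The list mean includes the tested genes and is not a count of cells, so this cannot decide on fewer cells. Of the 4 endothelial genes (median -0.99) 2 kept an adjusted p under 0.05 with the covariate. For Tek and Kdr the folds shrank from -1.46 ± 0.30 to -0.84 ± 0.27 and from -1.24 ± 0.28 to -0.61 ± 0.25. Fewer cells and lower expression cannot be told apart for the endothelial genes. Fewer cells are not excluded for either fall, since the scores of microglia, endothelial and border macrophage markers were all lower (by 0.761, 0.791 and 1.21). Without the 2 LPS libraries of low mitochondrial share the medians of the fallen genes were -2.12 and -1.76 against -2.58 and -1.87, although P2ry12 then missed the threshold (-1.68, adjusted p = 0.0606), which argues against that share as the whole cause, and lower expression of these genes in other cells carried through the sort remains a hypothesis.

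Markers of 8 other-cell lists were higher in 72 h than in 24 h saline libraries, with a median of list medians of 1.30; with an estimated correlation 6 kept their call, and the erythroid and ependymal lists did not (adjusted p = 0.125 and 0.357). The median was 0.943 (0.446 for the ependymal list alone) without the 2 saline libraries at 72 h with a mitochondrial share of 5.96% and 5.43%, and 0.935 among double-precision libraries, which argues against either as the whole cause, although only 3 and 118 genes then passed. A lower share of astrocytes would raise all other cell types. The microglia score rose by 1.34 more than the border macrophage score. Microglia minus border macrophage score was 2.73 ± 0.328 at 72 h (n = 4) and 1.40 ± 0.646 at 24 h (n = 5). The exact permutation test, two-sided, gave p = 0.0159, the smallest possible. This cannot decide the question, because the single-precision 24 h saline libraries had border macrophage scores near 0 (0.00986 to 0.141). At such values the pseudocount keeps equal fold rises from giving equal score changes. Among double-precision libraries the difference was 1.97, with the microglia score differing by 0.785 and the border macrophage score by -1.18. Only replicates 4 and 5 remained at 24 h there, so a lower share of astrocytes stays open. The number of genes detected also differed (16606 against 15447) and was not tested as a cause, and a change in the sort between days is a candidate explanation that stays open.

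Splits of the same libraries into groups of the same sizes were fitted for each count, with the real grouping as 1 of them. For 24 h females no other split called as many genes (649, 1 of 100 with the real one included, highest other 380). This was also so for 24 h males (1729, 1 of 100, highest other 423). It was so for the sexes in saline (10, 1 of 100, highest other 9). Saline 24 h against 3 h was alike (155, 1 of 100, highest other 141). At 3 h other splits called more genes than the real one (462, 3 of 100, highest other 2679). That was also the case for 24 h minus 3 h (138, 4 of 100, highest other 2100). Saline 72 h against 24 h was also surpassed (591, 2 of 100, highest other 1586). For these surpassed counts chance is not excluded. None of the ranks was adjusted over the contrasts. All counts come from the fit of all libraries, and for saline 72 h against 24 h a limma fit of the 2 groups alone called 0 genes. A larger share of splits reached the real count for 72 h (15, 2 of 35, highest other 2225). So it was for 72 h minus 24 h (67, 5 of 100, highest other 567). For the sexes after LPS it was 6 of 100 (14 genes, highest other 98). Chance is not excluded for these counts either. For the sex difference the real count is 0 (limma), so 100 of 100 splits reach it by construction and nothing follows from it (highest other 1). Splits that called several times the real count point to a structure of the samples: at 3 h the split with the most genes set saline replicates 1 to 3 with LPS replicates 2 and 3 against the rest, and at 72 h it set saline replicates 3 and 4 with LPS replicate 1. The other group of the 3 h split held the 3 libraries with the lowest mitochondrial shares at that time.

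A test for a single outlying library passed in 15 of 203 pairs of group and measure, where chance gives about 1 in 20, so the number itself is no sign of odd libraries. For Lcn2, C3, Ddx3y, Uty and Eif2s3y in females the other libraries lie at or near 0, where any small value passes, and the same holds for C3 and Xist in males. Female LPS 24 h replicate 4 had a microglia score of 3.33 (others 2.42 to 2.54), a border macrophage score of 2.20 (0.0363 to 0.255) and a leukocyte score of 2.87 (1.69 to 1.75), and it was the only double-precision library of its group. Male LPS 24 h replicate 3 had a border macrophage score of 2.03 (0.555 to 0.888). Male saline 24 h replicate 3 had log2(FPKM + 1) of 2.13 for Kdm5d (others 3.78 to 4.14), 5.22 for Eif2s3y (6.60 to 7.15), 8.30 for Aqp4 (7.52 to 7.72) and 0.0128 for C3 (others 0). Xist was at 0.375 in male LPS 24 h replicate 3 (0.00295 to 0.0952). Eif2s3y was at 0.277 in female saline 3 h replicate 1 (0 to 0.0438) and 0.309 in female saline 72 h replicate 2 (others 0). In female LPS 3 h replicate 4 Ddx3y was at 0.00844 (0 to 0.00209) and Uty at 0.0261 (0 to 0.00605). Female saline 72 h replicate 1 had Lcn2 at 0.231 (others 0) and female saline 3 h replicate 1 had C3 at 0.0765 (others 0). The LPS effect differed between 24 h and 3 h for 138 genes and between 72 h and 24 h for 67 genes by the interaction test.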

How the results depend on the processing

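The alternatives with the number format, the mitochondrial share, the libraries with few genes or a low mitochondrial share, and protein-coding genes only were chosen after the data were seen; the other alternatives were planned. Across all alternatives run, no named gene that passed the test with all libraries changed direction. Lcn2 and Gfap passed the test at 3 h and in both sexes at 24 h under every alternative run; log2 fold changes of Gfap ranged from 1.41 to 2.01 at 3 h, 2.48 to 2.67 in 24 h females and 1.66 to 2.33 in 24 h males. At 72 h, Lcn2 (2.51 to 6.39) did not pass in fits of only those groups, without the libraries of low mitochondrial share, or without LPS replicate 1. With a pseudocount of 0.1, 252 of 266 gene results kept direction and side of the threshold, with no filter 265 and with median-of-ratios rescaling 251; with the mitochondrial share as a covariate it was 226, and among double-precision libraries 88 of 202. With an estimated correlation 70 of 176 list results lost their call. The cause of the changes below was not tested except where fewer libraries or fewer genes were used by construction. Read depth is unknown, so its limits cannot be stated. An edgeR or DESeq2 count model was not run here because no counts were used.

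In the following, the sex difference is the male minus female LPS effect and the time differences are those of the female LPS effects. A pseudocount of 0.1 gave 77 genes for 24 h minus 3 h and 31 for the sexes after LPS. A filter at FPKM 5 gave 50 lower at 3 h, 8 higher at 72 h, 1 for the sex difference, and 77 and 361 for saline 24 h against 3 h and 72 h against 24 h. Rescaling to an equal FPKM sum gave 83 for saline 24 h against 3 h. Median-of-ratios rescaling gave 751 higher and 633 lower in males, 265 for saline 72 h against 24 h and 11 genes higher at both 24 h and 72 h. Fits of only the groups compared gave 303 higher and 58 lower in 24 h females, 2224 and 545 in males, 2 higher at 72 h, 1 for the sex difference, 45 for saline 24 h against 3 h and 0 for saline 72 h against 24 h (limma; 591 in the fit of all libraries), with 244 genes higher and 24 lower in both sexes and 2 higher at both 24 h and 72 h.

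Library quality weights, which lean on few libraries of a group, gave larger counts: 810 higher and 393 lower at 3 h, 1354 and 832 in 24 h females, 3419 and 1386 in males, 997 and 2617 at 72 h, 475 for 24 h minus 3 h, 5842 for 72 h minus 24 h, 226 for the sexes after LPS, 1124 and 6706 for saline 24 h against 3 h and 72 h against 24 h. Shared genes were then 330 higher at 3 h and 24 h, 976 higher and 370 lower in both sexes, and 63 higher at 24 h and 72 h, and the glycolysis list at 72 h turned to a median of -0.44. A replicate block gave 100 lower in 24 h females, 8 for 72 h minus 24 h and 11 higher at both 24 h and 72 h. No clear pairing by replicate number was seen. LPS and saline residuals of one number had correlations across genes from -0.0922 to 0.372 at 3 h and -0.186 to 0.108 in 24 h females. They ran from -0.276 to 0.255 in 24 h males and -0.404 to 0.278 at 72 h. The own number gave the highest correlation in 2 of 4 pairs at 3 h, 0 of 4 in 24 h females, 1 of 5 in 24 h males and 0 of 3 at 72 h. So few pairs cannot exclude pairing, and the replicate block is shown as an alternative alone. Requiring an absolute log2 fold change of 1 gave 82 lower in 24 h females, 665 higher and 139 lower in males, and 21 lower in both sexes.

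An estimated correlation left 8 of 17 lists called at 3 h, 7 of 20 in 24 h females, 6 of 16 in males and 8 of 24 at 72 h. The number format as a covariate gave 26 higher at 72 h, 33 and 162 for saline 24 h against 3 h and 72 h against 24 h, and 12 higher at both 24 h and 72 h. The mitochondrial share as a covariate gave 303 lower in 24 h females, 251 higher and 66 lower in males, 1 lower at 72 h, 270 and 44 for the 2 time differences, 276 for saline 24 h against 3 h, 191 higher in both sexes and 12 at both 24 h and 72 h. With it, the mitochondrially encoded list turned to 0.0135 at 3 h, 0.028 in males and -0.173 at 72 h, since the covariate removes that list by construction. Astrocyte identity and glycolysis in males turned to -0.0946 and -0.0856.

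Single-precision libraries alone gave 143 higher and 31 lower in males, and 115 higher and 10 lower in both sexes. Double-precision libraries alone, with 1 female LPS library at 24 h that is assumed to vary like the other groups, gave 25 and 2 in females, 383 and 50 in males, 30 and 1 for the time differences, 4 and 118 for saline 24 h against 3 h and 72 h against 24 h, and 24 higher and 1 lower in both sexes. With them the mitochondrially encoded (0.60) and neuron lists (0.40) turned in 24 h females, as did border macrophage markers in saline at 24 h against 3 h (0.26). Without the 2 libraries with the fewest genes 602 were lower in males. Without the libraries of low mitochondrial share 1 was lower at 72 h, 11 differed for 72 h minus 24 h and 3 for saline 72 h against 24 h, the mitochondrially encoded list turned to 0.0768 at 3 h and -0.52 at 72 h, and the ribosomal list at 72 h to 0.25. The list of cytosolic ribosomal proteins had a median of 0.0655 without LPS 72 h replicate 2 and -0.246 without replicate 1, against -0.11 with all libraries. Protein-coding genes alone gave 23 higher and 1 lower at 72 h, 1 for the sex difference, 5 for the sexes in saline and 12 higher at both 24 h and 72 h. The authors' adjusted p gave 154 lower at 3 h, 266 lower in 24 h females, 1809 lower in males, 134 higher and 5 lower at 72 h, and 175 for the sexes after LPS.

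Leaving out each library in turn gave 315 to 736 higher and 72 to 317 lower in 24 h females, 590 to 1574 higher and 103 to 500 lower in males, and 3 to 25 higher and 0 to 1 lower at 72 h (limma). It gave 105 to 215 for 24 h minus 3 h, 24 to 259 for 72 h minus 24 h, 0 to 1 for the sex difference, 11 to 88 for the sexes after LPS, and 41 to 213 and 33 to 904 for saline 24 h against 3 h and 72 h against 24 h. Counts at 3 h, from 291 to 415 higher and 58 to 103 lower, stayed within 1.5 times the value with all libraries.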

Other observations

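Gene groups not described above showed few called members. Of 25 astrocyte identity and transport genes 0 passed at 3 h and 72 h (limma) and 1 and 3 rose in 24 h females and males, with the gap junction gene Gjb6 at 0.88 ± 0.26 in females (adjusted p = 0.0491) and Aldoc at 1.05 ± 0.34 in males (adjusted p = 0.0489). Their calls were lost when any of 8 and 7 single libraries was left out. Sparc, a matricellular protein gene of the synapse-modulating list, rose in both sexes at 24 h (2.12 ± 0.33 and 1.91 ± 0.31), while Tnc, an extracellular matrix gene, fell by 1.67 (SE 0.27) in females and 1.11 (SE 0.26) in males, and the list did not pass in either sex (preset adjusted p = 0.573 and 0.6). The clock gene Per2 rose by 1.17 ± 0.25 in females and 1.25 ± 0.24 in males at 24 h, and Bhlhe40 by 1.47 ± 0.22 at 3 h, with no call for the clock list (adjusted p = 0.188, 0.0778 and 0.455 for these contrasts). Of 15 unfolded-protein genes 3 rose in males, with Sdf2l1 at 1.22 ± 0.32 (list adjusted p = 0.116; not called without LPS replicate 5, adjusted p = 0.0629). The list was lower in 24 h females (median -0.30, adjusted p = 0.0086) and differed between the sexes' LPS effects (median 0.65, adjusted p = 5.57e-06) with the preset correlation, but with an estimated one neither passed (0.355 and 0.487). In males Ndufa4 was the 1 of 26 nuclear oxidative phosphorylation genes that rose (1.13 ± 0.32, list adjusted p = 0.22), a call lost without any of 4 single libraries.

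Between the number formats at 24 h, 35 genes were higher and 179 lower in the 11 single-precision than in the 8 double-precision libraries (limma). The border macrophage list differed by a median of -1.73, erythroid markers by -1.22, microglia markers by -1.03 and immediate early genes by -0.65. Oligodendrocyte markers differed by -0.61, endothelial markers by -0.53, cell cycle genes by -0.53 and mural cell markers by -0.45. Immediate early genes were also higher in saline at 72 h than at 24 h (5 of 20 called, median 1.06, adjusted p = 0.126 with an estimated correlation).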
